A study of Mus musculus with 24 samples.

How the data were processed

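Total RNA of mouse liver tissue was amplified to cDNA, labelled with biotin and hybridised to whole-genome oligonucleotide arrays, 1 array per sample, with 24 arrays in 4 groups of 6. The deposited values were intensities, 1 per probe set and array on a linear scale, which the authors made with MAS5 (version not stated in the labels). Each array had been scaled so that its 2% trimmed mean was 500, which was checked on the values, and the arrays had not been quantile normalized. No raw array images or probe-level values were used here, and no genome build was named, so no coordinates are given.

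Of 45101 probe sets, 34945 were assigned to 1 gene, 932 to several genes and 9160 to none, and 64 were controls. Values were analysed as log2(intensity + 16). A probe set was kept when its 6th highest value lay above the 40th percentile of all values (66.3), which left 32762, and the brightest kept probe set stood for each gene, giving 14086 tested genes. The 5836 kept probe sets without a gene name were tested separately. HCC replicates 3 and 4 were near duplicates. Over 5483 bright probe sets the scaled median absolute deviation of their log2 differences was 0.17, against 0.35 to 0.83 in the other pairs of 60 within-group pairs. The mean of their log2 values therefore entered as 1 sample, which left 23 samples. That step was chosen after seeing the data, and the fit of 24 separate arrays was kept as an alternative.

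A linear model with 1 mean per group was fitted to all samples in limma 3.58.1 (R 4.3.3), with moderated variances that followed a trend over intensity, and 6 pairs of groups were compared. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, with a threshold of 0.05. Fold changes carry the moderated standard error (SE). Array measures were compared by two-sided exact permutation tests, adjusted over 12 tests, with the planned 3' to 5' ratios and the added measures adjusted separately. Principal components were computed on the log2 values of the tested genes.

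Gene lists were tested as groups with camera in limma at a preset correlation of 0.01 between genes, and again with an estimated correlation, adjusted over the 27 lists with at least 5 tested genes. They covered Wnt targets, the Wnt and Ras pathway, proliferation, oncofetal genes, imprinted genes, MAPK output, Notch and hedgehog, p53 targets, glycolysis and hypoxia, oxidative stress, biliary and progenitor markers, periportal and pericentral hepatocytes, secreted hepatocyte proteins, complement and coagulation, bile acids, xenobiotic metabolism, fatty acid oxidation, lipogenesis and cholesterol, male-biased and female-biased liver genes, and endothelial, stellate, macrophage, lymphocyte, granulocyte and erythroid markers. A list of sex-chromosome genes had 4 tested members, under the minimum, and its genes were read per array. Beside each list stand its members past the threshold over all genes and the number adjusted over the list alone. H19 and Hras were not named on the array.

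The comparisons, their tests in limma and camera, the lists and the alternatives for pseudocount, scaling, filter, probe sets, variance model, weights, separate controls, the 2 groups alone, leaving out each array and the replicate block were chosen before the data were examined. Chosen after were the alternatives that leave out several arrays, the added array measures, the test by hybridization controls, and the tests of hypotheses from single genes. Genes named in the text were the 8 in each direction with the largest fold change among called genes whose groups did not overlap (4 in the comparisons of the tumours with BDCA_nontumor), up to 4 members of each described list by adjusted p, and a fixed set of markers. Arrays with Xist intensity over 1000 were counted as carrying Xist signal. The log2 differences of HB and HCC were set against 50 simulations of unchanged groups with the shared controls, and the overlap of their calls against fits with separate controls. The method was tested on simulated data in the HCC against vehicle_normal design, where it recovered 24% of genes changed by 1 on the log2 scale and 79% of those changed by 2, with 5 false genes among 108 called. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.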

Results

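Gene expression was measured on 24 oligonucleotide arrays of liver tissue from B6C3F1 mice, 6 arrays in each of 4 groups. The groups were hepatoblastoma (HB, a liver tumour of embryonal type), hepatocellular carcinoma lying beside it (HCC), non-tumour liver beside the tumours (BDCA_nontumor here, BDCA_Normal in the titles, whose first part the labels do not spell out) and normal liver of vehicle controls (vehicle_normal). The protocols describe a bioassay of Ginkgo biloba extract in mice of both sexes, which the titles do not mention, and give no dose, sex or animal for any sample. The labels do not say that the samples of a group came from separate animals, so the p-values measure only the spread between these samples, part of which may be technical, and the number of arrays limits the precision. HCC replicates 3 and 4 were counted as 1 sample because their values lay far closer to each other than those of the other within-group pairs. Their r over the tested genes was 0.981, and the highest r of the other pairs was 0.957. HCC therefore had n = 5 and the other groups n = 6, which departs from the plan of 24 separate arrays and was decided after the values were seen.

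Every array had the same trimmed mean intensity of 500, while the median intensity was 165 ± 20.8 in HB, 104 ± 18.6 in HCC, 102 ± 25 in BDCA_nontumor and 92.5 ± 12.7 in vehicle_normal (mean ± SD, n = 6 arrays each). The HB samples stood apart on the first principal component, which held 60.6% of the variance. HB replicates 4 and 5 scored 131 and 135 there, against 169 to 180.5 for the other HB samples, and HCC replicate 1 lay at 6.54 on the next component, where the other HCC samples lay between -103 and -39.4. The ratio of 3' to 5' Gapdh signal, a measure of RNA quality, was 1.37 ± 0.23 in HB and 1.92 ± 0.19 in vehicle_normal (log2, SD, n = 6 each), with an adjusted p of 0.0260 in a two-sided exact permutation test. It was the only one of 12 such ratio tests to pass, and the nearest other was the Actb ratio of 0.52 ± 0.32 in HCC (n = 5) against 0.14 ± 0.10 in vehicle_normal (exact test, adjusted p = 0.0519).

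Xist, the RNA of the inactive X chromosome, read between 10287 and 12673 in vehicle_normal replicates 1, 2, 4 and 5 and in BDCA_nontumor replicate 6, and at most 252 in the other 19 arrays. The groups therefore differed in sex composition, with 4 of 6 vehicle_normal arrays and 1 of 6 BDCA_nontumor arrays carrying Xist signal and none of the HB or HCC arrays. Eif2s3y, a Y-linked gene, read 30.4 in HCC replicate 5 and between 1316 and 1931 in the other HCC arrays. Of the other Y-linked genes, Kdm5d read 403 in HCC replicate 5 (440 to 895 in the other HCC arrays) and Uty 71.1 (68.3 to 337).

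**Figure D1:**
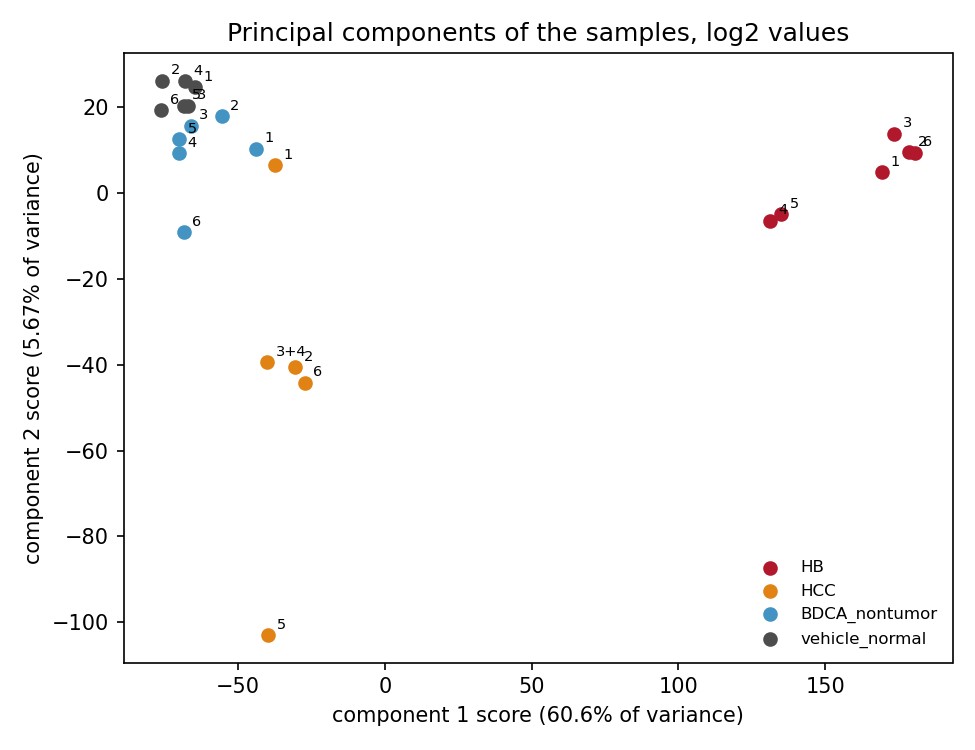
Scores of the 23 samples on principal components 1 and 2 of the log2 values of the tested genes, in arbitrary units, with each point numbered by its replicate (3+4 is the joint HCC sample). The 6 HB samples lie between 131 and 180.5 on component 1, above all other samples.

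**Figure D2:**
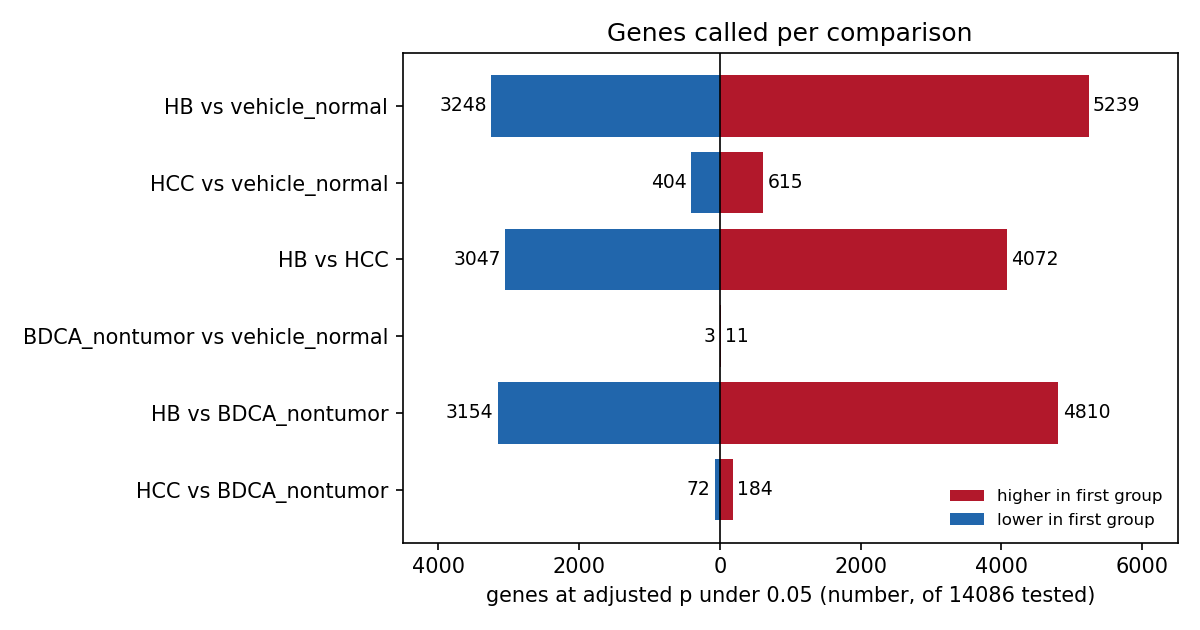
Number of genes past the threshold in each comparison of 14086 tested genes, with bars to the right for genes higher in the group named first and to the left for genes lower in it. The 3 comparisons with HB give 7119 to 8487 genes, and the 3 without it give 14 to 1019.

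HB was compared with vehicle_normal to find how hepatoblastoma tissue differed from normal liver (n = 6 and 6). Wif1, a secreted Wnt inhibitor, rose by 7.85 ± 0.47 on the log2 scale (SE), which is 230.1-fold (adjusted p = 2.95e-13). Hoxd9, a homeobox transcription factor, rose by 7.66 ± 0.30, or 202-fold (adjusted p = 2.55e-16). Cps1 and Otc, enzymes of the urea cycle, fell by 8.97 ± 0.69 and 8.72 ± 0.54 (adjusted p = 3.89e-11 and 4.88e-13), and Alb, the albumin gene, fell by 4.50 ± 0.78 (adjusted p = 2.34e-05). Alb read 28758 and 15782 in HB replicates 4 and 5 and 229 to 1630.3 in the other HB samples, so its fold is a mean over unlike samples. It read 32099 to 51639.6 in vehicle_normal, near the top of the scale, where a fold can come out too small. In each of these 5 genes every HB sample lay on the same side of every vehicle_normal sample. In 32 of the 60 named genes called in this comparison the median of 1 group lay below the filter value of 66.3, so the size and rank of such a fold depend on the pseudocount of 16. Hoxd9, at 2.35 to 9.85 in vehicle_normal, rose by 9.36 with a pseudocount of 1 and by 6.01 with 64, and Wif1 by 8.25 and 7.01. Cps1, at 0.72 to 24.2 in HB apart from replicate 4 (1234), fell by 10.29 and 7.70. The other genes with the largest rises were Speer4cos (8.40), Fxyd6 (7.87), Ptn, a secreted growth factor (7.86), Prph, a neuronal intermediate filament (7.75), Spock2 (7.71) and Pla2g2a, a secreted phospholipase (7.71). The other genes with the largest falls were Upp2 (-9.07), Cyp3a25 (-9.0), Cyp2f2 (-8.78), Mup3, a major urinary protein (-8.63), Hamp2, a hepcidin (-8.58), and Mat1a, an enzyme of S-adenosylmethionine synthesis (-8.49). Adjusted p values of these 12 genes lay between 3.72e-15 and 1.82e-07.

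Targets of Wnt signalling rose together in HB against vehicle_normal: 19 of 19 tested list members were higher, with a median of 3.49 (camera adjusted p = 4.99e-08, and adjusted p = 0.0406 with an estimated correlation). Apcdd1 rose by 7.64 ± 0.53, Nkd1 by 4.55 ± 0.30 and Axin2 by 4.46 ± 0.45, each a negative regulator of the pathway, while Lgr5 stood at 2.08 ± 0.90 with adjusted p = 0.0472 and overlapping groups. All 23 tested proliferation genes rose as well, with a median of 2.48 (camera adjusted p = 1.08e-05, and adjusted p = 0.193 with an estimated correlation), among them Top2a (4.02 ± 0.54), Mki67 (3.76 ± 0.57) and Plk1 (2.82 ± 0.39). Of 10 oncofetal genes 8 rose and none fell, with a median of 2.00 (camera adjusted p = 0.0229, and adjusted p = 0.186 with an estimated correlation). Sox11 (3.91 ± 0.38), Sox4 (3.29 ± 0.29) and Gpc3 (2.34 ± 0.69) were among those that rose, and Afp stood at -0.19 ± 0.66 (adjusted p = 0.822). Of 15 genes of MAPK output 9 rose and 1 fell, with a median of 1.01 (camera adjusted p = 0.0239, and adjusted p = 0.267 with an estimated correlation), led by Etv5 (4.72 ± 0.39) and Dusp4 (4.23 ± 0.50), and its median became 1.65 without the 5 arrays with Xist signal (adjusted p = 0.0317).

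Transcripts of hepatocyte functions fell in HB across lists. All 23 complement and coagulation genes fell (median -6.28), as did all 15 bile acid genes (-6.17) and all 13 periportal genes (-6.69), together with 16 of 17 xenobiotic metabolism genes (-5.02) and 13 of 17 genes of fatty acid oxidation under PPARα (-2.46). Camera adjusted p values of these 5 lists lay between 6.61e-19 and 6.87e-08, and all 5 held with an estimated correlation (adjusted p = 0.0406 to 0.0468). Examples were C8g (-6.13 ± 0.28), the bile acid transporter Slc10a1 (-6.17 ± 0.30), Akr1d1 (-7.32 ± 0.37), the gluconeogenic enzyme Pck1 (-7.86 ± 0.47), Fmo1 (-6.14 ± 0.36) and Cd36 (-5.48 ± 0.37). The 13 secreted hepatocyte proteins (median -6.29, with Hpx at -7.59 ± 0.61), 12 of 14 pericentral genes (-5.06, with Cyp2c50 at -7.44 ± 0.40) and 15 of 17 lipogenesis and cholesterol genes (-2.69, with Insig1 at -4.01 ± 0.26) fell too, at camera adjusted p = 1.05e-08, 2.03e-07 and 6.13e-08. With an estimated correlation these 3 lists had adjusted p = 0.186, 0.140 and 0.186.

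Markers of other liver cells and of sex-biased hepatocyte genes fell in the same comparison. Of 16 macrophage markers 15 fell and 1 rose (median -3.03), with Cd5l at -7.16 ± 0.59 and Timd4 at -3.78 ± 0.36. Of the endothelial markers 12 of 16 fell (-1.88), with Clec4g at -7.16 ± 0.41, and 9 of 12 lymphocyte markers fell and 1 rose (-1.57), with Ighm at -6.68 ± 0.68. Of the female-biased genes 8 of 10 fell (-5.11), with Cyp2b13 at -6.82 ± 0.82, and of the male-biased genes 4 of 6 (-3.66), with Nudt7 at -4.70 ± 0.29 and Cyp2d9 at -5.38 ± 0.81. Camera adjusted p values of these 5 lists were 5.78e-07, 1.85e-05, 0.00734, 1.24e-04 and 0.00533, and with an estimated correlation the adjusted p was 0.193, 0.193, 0.236, 0.193 and 0.193. The lymphocyte, female-biased and male-biased medians became -0.92, -2.84 and -5.64 without the 5 arrays with Xist signal, and the lists kept their calls.

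The remaining 10 lists did not pass the threshold in camera in HB, though many of their members passed. Among 16 imprinted genes 9 rose and 1 fell (camera adjusted p = 0.134): Igf2, a fetal growth factor, rose by 5.99 ± 0.55, Cdkn1c by 4.55 ± 0.47 and Grb10 by 3.05 ± 0.38, and Slc38a4 fell by 3.26 ± 0.30. Ctnnb1, which encodes β-catenin, rose by 0.75 ± 0.15 (adjusted p = 8.44e-05) in the list of Wnt and Ras pathway genes, where 6 of 9 rose and 1 fell (camera adjusted p = 0.229). Of 16 Notch and hedgehog genes 9 rose and 1 fell (camera adjusted p = 0.0543). Of 15 glycolysis and hypoxia genes 9 rose and 2 fell (0.123), with Aldoa at 1.65 ± 0.22, and of 11 p53 targets 6 rose and 1 fell (0.192), with Phlda3 at 4.26 ± 0.34 and Cdkn1a at 3.75 ± 0.58. Biliary and progenitor markers were split, with 5 of 11 higher and 3 lower; their median was 0.99 and their mean 0.13, while camera pointed downward (adjusted p = 0.939). Cd24a rose by 4.2 ± 0.46 and Krt7 by 2.31 ± 0.54, Krt8 fell by 5.04 ± 0.70, and Krt19 stood at 1.35 ± 0.51 (adjusted p = 0.0239). Fewer members rose than fell among 10 oxidative stress genes (1 and 4, camera adjusted p = 0.0955), 17 stellate and fibroblast markers (3 and 6, 0.134) and 9 granulocyte markers (0 and 5, 0.0544, with Lcn2 at -3.88 ± 0.81), and 6 erythroid markers had 3 higher and 2 lower (0.844). Adjusted over the list alone, the counts differed only for the lipogenesis list (16 lower) and the stellate list (4 higher and 7 lower). Glul, the pericentral glutamine synthetase, stood at -0.78 ± 0.28 (adjusted p = 0.0179), and Dlk1 at 0.86 ± 0.43 (adjusted p = 0.09).

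In total 8487 genes passed in HB against vehicle_normal in limma, 5239 higher and 3248 lower, and 6555 differed by at least 2-fold. The groups did not overlap in 37.6% of the tested genes, where chance gives 0.216%. The median log2 difference of all tested genes was 0.34, and the share of called genes that were higher, 61.7%, became 48.5% after quantile normalization and 46.1% after median centring. Both scalings moved the median of all genes to -0.03. With a pseudocount of 1 Lgr5 lost its call (adjusted p = 0.116). Lgr5 and Krt19 lost theirs under both scalings, at adjusted p = 0.1045 and 0.271 after quantile normalization, as did Glul after quantile normalization (-0.02, adjusted p = 0.939). Leaving out 1 array ended the calls of Lgr5 (without HB replicate 1, adjusted p = 0.0840), Krt19 (without HB replicate 2, 0.0782) and Glul (without HB replicate 3, 0.0502). Without the 5 arrays with Xist signal 4 of the 60 named genes called lost their call: Krt7 (1.62, adjusted p = 0.0772), Lgr5 (2.26, 0.131), Krt19 (1.20, 0.179) and Glul (-0.62, 0.202).

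HCC was compared with vehicle_normal (n = 5 and 6) to find how the neighbouring carcinoma differed from normal liver. Gpc3, a glypican of fetal liver, rose by 6.40 ± 0.72 (SE), which is 84.3-fold (adjusted p = 1.79e-05), and Bex1 by 5.30 ± 0.60 (adjusted p = 1.79e-05). Sult2a8, a sulfotransferase, fell by 6.77 ± 0.56, or 109-fold (adjusted p = 6.17e-08), and Mup10, a major urinary protein, fell by 6.42 ± 0.79 (adjusted p = 3.55e-05). In each of these 4 genes every HCC sample lay on the same side of every vehicle_normal sample. Akr1c18 (6.07), Igdcc4 (5.66), Tff3 (5.16), Plat, the tissue plasminogen activator (5.01), Slpi, a protease inhibitor (4.91), and Cpe (4.84) also rose, with adjusted p values from 2.94e-05 to 0.00103. Mup3 (-4.81), Hectd2 (-4.72), 1810046K07Rik (-4.57), Cyp2f2 (-4.53), Hamp2 (-4.30) and C730036E19Rik (-4.17) fell, with adjusted p values from 1.83e-04 to 0.0197. Hamp2 lost its call without HCC replicate 2 or 5 (adjusted p = 0.0547 and 0.0580).

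Of the lists, 7 were shifted upward in HCC against vehicle_normal. Among Wnt targets 6 of 19 rose (median 0.85, camera adjusted p = 3.30e-04), among them Myc (1.51 ± 0.33) and Lef1 (2.54 ± 0.64, a call lost without HCC replicate 2 at adjusted p = 0.0572). Among proliferation genes 6 of 23 rose (0.84, 3.85e-04), with Plk1 at 2.01 ± 0.41. Of 15 glycolysis genes 5 rose (0.86, 3.85e-04), with Aldoa at 1.15 ± 0.23, and of 11 p53 targets 3 rose (0.72, 0.00326), with Cdkn1a at 3.62 ± 0.61 and Phlda3 at 2.10 ± 0.36. In the MAPK list 3 of 15 rose (0.95, 0.00646), with Ier3 at 3.24 ± 0.44, and in the oncofetal list 3 of 10 (0.55, 0.0164), with Afp at 3.13 ± 0.70. In the biliary and progenitor list 3 of 11 rose (0.76, 0.0187), with Cd24a at 1.69 ± 0.48, a call lost without HCC replicate 6 (adjusted p = 0.111). None of the 7 held with an estimated correlation (adjusted p = 0.312 to 0.376). The numbers higher in these 7 lists were 7, 10, 8, 6, 5, 4 and 4 adjusted over the list alone, with 1 p53 target lower. The biliary and progenitor list lost its call without HCC replicate 6 (adjusted p = 0.0929) and the MAPK list without HCC replicate 5 (0.0618). The glycolysis median became 0.50 without HCC replicate 2, the oncofetal median 0.87 without HCC replicate 5, and the biliary median 0.48 without vehicle_normal replicate 2. Without the 5 arrays with Xist signal the oncofetal and the biliary and progenitor lists lost their calls (0.0527 and 0.0669), with medians of 0.60 and 0.61. The MAPK median became 0.57 (0.0174).

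The other 9 called lists were shifted downward in HCC. Periportal genes had 5 of 13 lower (median -1.29, camera adjusted p = 1.38e-06), with Etnppl at -3.31 ± 0.69 and Otc at -2.73 ± 0.56, and bile acid genes 3 of 15 (-0.89, 1.33e-04), with Slc10a1 at -1.51 ± 0.32. Macrophage markers had 1 lower and 1 higher of 16 (-0.93, 1.33e-04), with Timd4 at -1.85 ± 0.38. HCC replicate 5 stood apart there, with a macrophage mean of 7.39 against 9.91 to 10.90 in the other HCC samples, and the median became -0.43 without it (adjusted p = 0.0117) and -1.42 without HCC replicate 1. Lipogenesis genes had 2 of 17 lower (-0.52, 3.85e-04), complement genes 2 of 23 (-0.39, 8.17e-04), lymphocyte markers 2 of 12 (-0.38, 0.0167) and pericentral genes 2 of 14 (-0.43, 0.0187), the last with Cyp2c50 at -2.11 ± 0.42. Ighm, a lymphocyte marker, stood at -3.26 ± 0.72, while another of its probe sets read 1.13. Of 10 female-biased genes 1 was lower (-1.41, 0.0178), Cyp2b13 (-4.68 ± 0.86), and of 6 male-biased genes 1 (-1.04, 0.0182), Nudt7 (-2.49 ± 0.30), beside the Xist signal of 4 vehicle_normal arrays. Without the 5 arrays with Xist signal the female-biased list turned upward (median 1.60, adjusted p = 0.0116), Cyp2b13 stood at -1.38 (adjusted p = 0.441), the male-biased median became -2.94, the bile acid median -1.42, and the lymphocyte list lost its call (0.361). None of these 9 lists held with an estimated correlation (adjusted p = 0.312 to 0.443). The numbers lower, adjusted over the list alone, were 6, 5, 7, 2, 5, 2, 2, 2 and 2 in the order given, with 1 higher gene in each of the macrophage, female-biased and male-biased lists. Of these 9 lists 5 lost their call without 1 array. These were lipogenesis (-0.21 without HCC replicate 1, adjusted p = 0.141), lymphocyte (-0.24 without HCC replicate 1, 0.0775, and -0.21 without vehicle_normal replicate 5, 0.159) and pericentral (-0.52 without HCC replicate 1, 0.0775, and -0.21 without 6, 0.202). The others were female-biased (without HCC replicate 2, 0.101, or vehicle_normal replicate 1 or 2, 0.0636 and 0.0906) and male-biased (without vehicle_normal replicate 3 or 6, 0.0710 and 0.137). The male-biased median was -0.48 without HCC replicate 5, and the female-biased -2.13 without vehicle_normal replicate 6.

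The other 11 lists (hepatocyte-secreted, xenobiotic, fatty acid oxidation, imprinted, Notch and hedgehog, oxidative stress, Wnt and Ras pathway, endothelial, stellate, granulocyte and erythroid) had camera adjusted p values from 0.175 to 0.927. They held 7 higher and 4 lower members, and 2 further imprinted genes were lower over the list alone. Grb10 rose by 2.42 ± 0.40, and Lcn2 stood at 2.90 ± 0.85 (adjusted p = 0.0383) and lost its call without HCC replicate 1 (0.0809). The endothelial, stellate and Wnt and Ras pathway medians of 0.35, 0.09 and 0.14 were positive where camera pointed downward, the fatty acid oxidation median of -0.03 was negative where it pointed upward, and the granulocyte mean (0.02) and median (-0.22) differed in sign. Igf2 stood at 1.94 ± 0.57 (adjusted p = 0.0384), Axin2 at 1.53 ± 0.47 (0.0457) and Mki67 at 2.07 ± 0.60 (0.0360), and these 3 calls were lost without HCC replicate 5 (adjusted p = 0.104, 0.113 and 0.102). The values of Ctnnb1 (-0.09 ± 0.15), Glul (-0.08 ± 0.29), Lgr5 (-0.23 ± 0.94), Dlk1 (0.50 ± 0.45), Alb (-0.41 ± 0.82) and Krt19 (0.76 ± 0.53) did not pass (adjusted p = 0.437 to 0.925).

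In limma 1019 genes passed in HCC against vehicle_normal, 615 higher and 404 lower, and 783 differed by at least 2-fold. The groups did not overlap in 5.08% of the tested genes, where chance gives 0.433%. The share of called genes that were higher, 60.4%, became 51.7% after quantile normalization and 43.7% after median centring. Under these scalings 8 of the 44 named genes called lost their call. After quantile normalization they were Igf2 (adjusted p = 0.0831), Axin2 (0.0771), Mki67 (0.0721), Cd24a (0.0545), C8g (0.0540), Sox4 (0.0976), Insig1 (0.117) and Dusp4 (0.116), and after median centring Igf2 (0.0516), Axin2 (0.0652) and Dusp4 (0.0698). Without the 5 arrays with Xist signal, which left 2 vehicle_normal arrays, 193 genes passed, and 28 of the 44 named genes called lost their call. Among these 28 were Afp (3.61, adjusted p = 0.104), Tff3 (4.24, 0.0775), Mup3 (-5.18, 0.0967), Hectd2 (-4.60, 0.0919), Hamp2 (-3.76, 0.320), Myc (1.32, 0.212), Plk1 (2.11, 0.101), Otc (-2.72, 0.146), Slc10a1 (-1.57, 0.133), Aldoa (0.99, 0.150), Cd24a (1.45, 0.367), Ighm (-2.38, 0.328) and Timd4 (-1.26, 0.270). Of the 44, 13 lost their call without some single array, Axin2, Lcn2, Igf2, Cd24a and Mki67 without any 1 of several, and 5 with a pseudocount of 1, among them Axin2 (0.0530), Igf2 (0.0582) and Lcn2 (0.0966). Without HCC replicate 5, 656 genes passed.

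HB and HCC shared part of their differences from vehicle_normal. None of their arrays carried Xist signal and 4 of 6 vehicle_normal arrays did, so sex differences may be among the shared ones. In limma 435 genes were higher in both and 335 lower in both, against 229 and 93.2 from independent calls, and 43 went opposite ways. With separate vehicle_normal arrays for each tumour, 256 and 301 genes were called in both in the same direction. With HB against replicates 1 to 3 and HCC against 4 to 6, 147 were higher and 109 lower, against 73.7 and 25.2 from independent calls. With the sets exchanged 171 were higher and 130 lower, against 88.3 and 33.3. Both sets held arrays with Xist signal, so separate controls do not remove a sex difference. Across genes, which are not independent replicates, the log2 differences had r = 0.50, against 0.48 in 50 simulations of unchanged groups with the shared controls, and a covariance of 0.71 against 0.07.

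HB was compared with HCC (n = 6 and 5) to find how the tumour types differed. Hoxd9 was higher in HB by 7.35 ± 0.31 (SE), or 164-fold (adjusted p = 3.60e-15), and Gbx2, another homeobox gene, by 7.15 ± 0.33 (adjusted p = 1.46e-14). Apcs, the serum amyloid P component, was lower in HB by a log2 difference of -7.72 ± 0.77 (adjusted p = 6.22e-09), and Cps1 by one of -7.68 ± 0.73 (adjusted p = 2.64e-09). Every HB sample lay on the same side of every HCC sample in these 4 genes, and in each the lower group had a median below 66.3, so these folds too depend on the pseudocount: Hoxd9 stood at 8.96 with a pseudocount of 1 and 5.85 with 64, Gbx2 at 8.06 and 5.94, Apcs at -9.18 and -6.51, and Cps1 at -9.01 and -6.42. Gpc3 (-4.06 ± 0.72, adjusted p = 4.69e-05) and Afp (-3.32 ± 0.70, adjusted p = 3.14e-04) were lower in HB, while Igf2 (4.04 ± 0.57, adjusted p = 2.10e-06) and Ctnnb1 (0.85 ± 0.15, adjusted p = 5.21e-05) were higher. Slc14a1, a urea transporter (7.18), Wif1 (7.11), Speer4cos (7.03), Hoxd8 (7.02), Speer8-ps1 (6.94) and Fxyd6 (6.92) were also higher, and Cyp2d9 (-7.71), Hrg (-7.64), Mat1a (-7.56), Cyp3a25 (-7.46), Cyp2c70 (-7.37) and Hpx (-7.34) lower, with adjusted p values from 1.11e-12 to 3.30e-08.

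Wnt targets were higher in HB than in HCC in 18 of 19 genes (median 2.31, camera adjusted p = 1.60e-07, and adjusted p = 0.0348 with an estimated correlation), including Apcdd1 (5.62 ± 0.56), Nkd1 (3.82 ± 0.32) and Axin2 (2.93 ± 0.47). Proliferation genes were higher in 19 of 23 (1.61, camera adjusted p = 6.78e-04, and adjusted p = 0.330 with an estimated correlation). Lower in HB were 23 of 23 complement genes (median -5.80), 15 of 15 bile acid genes (-4.73), 15 of 17 xenobiotic genes (-4.79) and 17 of 17 genes of fatty acid oxidation (-2.62), at camera adjusted p = 1.26e-19, 5.45e-12, 3.55e-11 and 1.10e-09. These 4 held with an estimated correlation (adjusted p = 0.0348 to 0.0425). The 9 further lists shifted downward were secreted hepatocyte proteins (13 of 13 lower), periportal (12 of 13), pericentral (13 of 14), endothelial (13 of 16), macrophage (10 of 16, with 1 higher), lipogenesis (14 of 17), female-biased (8 of 10), male-biased (3 of 6) and oxidative stress (6 of 10). Their camera adjusted p values ran from 5.67e-09 to 0.0421, and with an estimated correlation the adjusted p was 0.0903 to 0.343. The male-biased list lost its call without HB replicate 1 or 2 (adjusted p = 0.0522 and 0.0512) and without HCC replicate 1 or 2 (0.0874 and 0.0525).

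The other 12 lists had camera adjusted p values from 0.0837 to 0.937 in HB against HCC. The erythroid median of -0.07 and mean of 0.09 differed in sign there, and the p53 list had a median of -0.00 with a mean of 0.12. Among their members Etv5 (4.41 ± 0.41), Cdkn1c (4.13 ± 0.49), Sox11 (3.48 ± 0.39), Cd24a (2.51 ± 0.48) and Phlda3 (2.16 ± 0.36) were higher in HB, and Krt8 (-5.44 ± 0.73), Lcn2 (-6.78 ± 0.85) and Egfr (-3.98 ± 0.56) lower. Counts adjusted over the list alone differed for the macrophage (13 lower), lymphocyte (6 lower, against 5), Wnt and Ras pathway (6 higher, against 4) and p53 (0 lower, against 1) lists. Alb stood at -4.10 ± 0.82 (adjusted p = 1.88e-04), Mki67 at 1.69 ± 0.60 (0.0215), Lgr5 at 2.31 ± 0.94 (0.0425), Glul at -0.70 ± 0.29 (0.0473), Krt19 at 0.59 ± 0.53 (0.363) and Dlk1 at 0.35 ± 0.45 (0.536). In limma 7119 genes passed, 4072 higher and 3047 lower in HB, and 5460 by at least 2-fold. The groups did not overlap in 28.6% of the tested genes, where chance gives 0.433%. The median of all genes was 0.19, and the share higher, 57.2%, became 46.2% after quantile normalization and 43.5% after median centring; Glul (adjusted p = 0.556) and Lgr5 (0.0561) lost their calls after quantile normalization and Lgr5 (0.0764) and Mki67 (0.0549) after median centring. With a pseudocount of 1 Glul (0.0505) and Lgr5 (0.0688) lost theirs. Leaving out 1 array ended the calls of Glul (without HCC replicate 5, adjusted p = 0.146), Lgr5 (without HCC replicate 1, 0.174) and Mki67 (without HCC replicate 6, 0.0634).

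BDCA_nontumor was compared with vehicle_normal (n = 6 and 6) to find how the liver beside the tumours differed from control liver, and few genes passed the threshold. Mt2, a metallothionein, rose by 2.04 ± 0.32 (SE), which is 4.12-fold (adjusted p = 0.00752), and Gm19619 by 2.5 ± 0.36 (adjusted p = 0.00326). Lepr, the leptin receptor, rose by 3.53 ± 0.67 (adjusted p = 0.0305), Gpx3, an extracellular glutathione peroxidase, by 2.5 ± 0.45 (0.0220), and Alas1, the rate-limiting enzyme of haem synthesis in liver, by 1.94 ± 0.38 (0.0408). Crybb3 (1.78), Cep85 (1.70) and Nolc1 (1.49) also rose, and Serpinb1a (-2.18 ± 0.41) and Sdhc, a subunit of succinate dehydrogenase (-1.03 ± 0.18), fell, with adjusted p values from 0.0220 to 0.0482. In each of these 10 genes every BDCA_nontumor sample lay on the same side of every vehicle_normal sample.

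Lipogenesis and cholesterol genes were shifted downward in BDCA_nontumor (median -0.75 over 17 genes, camera adjusted p = 8.54e-07, and adjusted p = 0.937 with an estimated correlation), with Insig1 at -0.75 ± 0.26 (adjusted p = 0.276). BDCA_nontumor replicate 1 stood apart, with a list mean of 9.92 against 11.59 to 12.42 in the other 5, and without it the median was -0.48 (camera adjusted p = 6.17e-04). Lymphocyte markers (-1.08 over 12 genes, camera adjusted p = 1.05e-06, and adjusted p = 0.257 with an estimated correlation) and stellate and fibroblast markers (-0.62 over 17 genes, 0.00410, and adjusted p = 0.937 with an estimated correlation) were shifted downward too, and the stellate list lost its call without BDCA_nontumor replicate 4 (adjusted p = 0.0823). The lymphocyte median became -0.71 without the 5 arrays with Xist signal (adjusted p = 0.0438). No member of these 3 lists passed over all genes, and 4, 5 and 0 were lower adjusted over the list alone. The other 24 lists had camera adjusted p values from 0.0768 to 0.943 and no member past the threshold over all genes, and 4 members were higher and 7 lower adjusted over the list alone. The female-biased, male-biased and complement medians (0.39, 0.03 and 0.01) were positive where camera pointed downward. Without the 5 arrays with Xist signal the female-biased median was larger and camera pointed upward, as given with the processing alternatives. The granulocyte median (-0.04) was negative where it pointed upward, and the imprinted and the Wnt and Ras pathway means (0.02 each) were positive where medians and camera were negative. The values of Afp (0.20 ± 0.66), Igf2 (-0.53 ± 0.55), Gpc3 (0.94 ± 0.69), Axin2 (0.53 ± 0.45), Ctnnb1 (-0.15 ± 0.15), Glul (-0.33 ± 0.28), Lgr5 (-0.52 ± 0.90), Dlk1 (0.57 ± 0.43), Mki67 (0.40 ± 0.57), Alb (-0.30 ± 0.78) and Krt19 (-0.11 ± 0.51) did not pass.

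In limma 14 genes passed in BDCA_nontumor against vehicle_normal, 11 higher and 3 lower, all by at least 2-fold, and 1449 had an unadjusted p under 0.05. The share higher, 78.6%, became 45.5% after quantile normalization and 63.2% after median centring, and the groups did not overlap in 1.22% of the tested genes, where chance gives 0.216%. Quantile normalization ended the calls of Alas1 (adjusted p = 0.0645), Crybb3 (0.0654) and Nolc1 (0.0768), and median centring that of Crybb3 (0.0533). Leaving out 1 array gave 9 genes without HB replicate 1, 33 and 23 without HCC replicates 1 and 5, 2, 3, 7 and 7 without BDCA_nontumor replicates 1, 3, 4 and 5, and 3, 3 and 2 without vehicle_normal replicates 1, 2 and 4. In these fits 8 of the 10 named genes lost their call at least once, with adjusted p up to 0.129 (Nolc1 without BDCA_nontumor replicate 1), the exceptions being Mt2 and Gm19619. With a pseudocount of 1 Alas1, Nolc1 (0.0505 each), Crybb3 and Serpinb1a (0.0765 each) lost theirs. Without the 5 arrays with Xist signal 10 genes passed, and of the 10 named genes only Lepr kept its call. That fit had 2 vehicle_normal arrays, and the 14 genes kept a median share of 0.941 of their log2 fold change, all in the same direction. Also among the 14 were Tmc5, Slc6a9 and Mup10, whose groups overlapped, and Dmxl2, whose groups did not. These 4 are named only after their values were seen.

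HB was compared with BDCA_nontumor (n = 6 and 6) to set the tumour against its neighbouring liver. Islr was higher in HB by 8.30 ± 0.43 (SE), or 315-fold (adjusted p = 3.26e-14), and Ptn by 8.29 ± 0.49 (adjusted p = 2.78e-13), with Speer4cos (8.28) and Pla2g2a (8.27) next. Cyp3a25 was lower by a log2 difference of -8.83 ± 0.50 (adjusted p = 1.34e-13), with Orm1, an acute-phase protein (-8.68), Upp2 (-8.67) and Cps1 (-8.62) next, and the groups did not overlap in these 8 genes. In 23 of the 48 named genes called the median of 1 group lay below 66.3, and their folds depend on the pseudocount, as with Islr (9.46 with 1 and 6.91 with 64) and Cyp3a25 (-10.40 and -7.50). Wnt targets were higher in 19 of 19 genes (median 2.86, camera adjusted p = 4.68e-08, and adjusted p = 0.0393 with an estimated correlation). In turn 23 of 23 complement, 15 of 15 bile acid, 13 of 13 periportal, 14 of 17 xenobiotic and 16 of 17 fatty acid oxidation genes were lower (camera adjusted p = 9.60e-20 to 1.10e-09, and adjusted p = 0.0393 to 0.0460 with an estimated correlation). The other 12 called lists had 20 of 23 proliferation, 10 of 15 MAPK, 6 of 10 oncofetal and 10 of 16 Notch and hedgehog genes higher. They had 13 of 13 secreted hepatocyte, 13 of 14 pericentral, 14 of 16 macrophage, 14 of 17 lipogenesis, 11 of 16 endothelial, 8 of 10 female-biased, 3 of 6 male-biased and 4 of 9 granulocyte genes lower. Camera adjusted p values were 6.63e-09 to 0.0267, and adjusted p = 0.122 to 0.249 with an estimated correlation. The remaining 9 lists had camera adjusted p values from 0.104 to 0.870. Over the biliary and erythroid lists the medians were 0.59 and 0.09 where camera pointed downward. Counts adjusted over the list alone differed for the macrophage (15 lower), oncofetal (7 higher) and p53 (7 higher, against 5) lists.

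Igf2 (6.52 ± 0.55), Axin2 (3.93 ± 0.45), Mki67 (3.36 ± 0.57) and Ctnnb1 (0.91 ± 0.15) were higher and Alb (-4.20 ± 0.78) lower in HB than in BDCA_nontumor, with adjusted p values from 1.95e-10 to 6.25e-05. Krt19 stood at 1.46 ± 0.51 (adjusted p = 0.0166), Lgr5 at 2.61 ± 0.90 (0.0156), Gpc3 at 1.40 ± 0.69 (0.0854), Glul at -0.46 ± 0.28 (0.166), Afp at -0.39 ± 0.66 (0.632) and Dlk1 at 0.29 ± 0.43 (0.591). In limma 7964 genes passed, 4810 higher and 3154 lower, with 6025 by at least 2-fold, and the groups did not overlap in 32.5% of the tested genes, where chance gives 0.216%. The median of all genes was 0.28, and the share higher, 60.4%, became 48.6% after quantile normalization and 45.1% after median centring, and Krt19 lost its call under both (adjusted p = 0.135 and 0.0627). Krt19 also lost it without BDCA_nontumor replicate 5 (0.0566), and Lgr5 without BDCA_nontumor replicate 1 (0.0528).

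HCC was compared with BDCA_nontumor (n = 5 and 6) to set the carcinoma against its neighbouring liver. Bex1 rose by 5.52 ± 0.60 (SE), which is 46.0-fold (adjusted p = 2.39e-05), and Phgdh, the enzyme of the first step of serine synthesis, by 5.33 ± 0.64 (adjusted p = 5.75e-05). Gpc3 rose by 5.46 ± 0.72 (adjusted p = 1.20e-04) and Akr1c18 by 5.16 ± 1.08 (0.0109), while Sult3a1, a sulfotransferase, fell by 5.43 ± 1.18 (0.0143) and Sult2a8 by 4.21 ± 0.56 (1.20e-04). Slco2b1, an organic anion transporter (-2.63 ± 0.45, 0.00254), and Lrtm1 (-2.50 ± 0.58, 0.0228) fell as well, and the groups did not overlap in these 8 genes. Phlda3 (2.91 ± 0.36), Grb10 (2.07 ± 0.40) and Sox4 (1.39 ± 0.30) rose and Nudt7 (-1.46 ± 0.30) fell, with adjusted p values from 5.75e-05 to 0.0140. Afp stood at 2.92 ± 0.70 (adjusted p = 0.0257), Igf2 at 2.47 ± 0.57 (0.0226) and Cyp2f2 at -3.17 ± 0.76 (0.0261), and these 3 calls were lost without HCC replicate 5 (adjusted p = 0.1, 0.0809 and 0.102), as was that of Sult3a1 (0.0538). Afp and Igf2 also lost theirs without the 5 arrays with Xist signal (0.0703 and 0.0656). Without HCC replicate 6 Sox4 lost its call (adjusted p = 0.0533), and without BDCA_nontumor replicate 5 so did Lrtm1 (0.0612), as Cyp2f2 did with a pseudocount of 1 (0.0656).

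Of the 27 lists 17 were shifted in HCC against BDCA_nontumor, and none of them held with an estimated correlation (adjusted p = 0.174 to 0.384). Upward were MAPK output (median 0.90, 1 of 15 higher, camera adjusted p = 8.04e-06), proliferation (0.82, 0 of 23, 1.79e-05), Wnt targets (0.76, 0 of 19, 4.84e-04), p53 targets (0.44, 1 of 11, 0.00121), biliary and progenitor markers (0.87, 0 of 11, 0.00429), the oncofetal list (0.49, 3 of 10, 0.00467), glycolysis (0.51, 0 of 15, 0.0137), Notch and hedgehog (0.41, 0 of 16, 0.0140), stellate markers (0.57, 1 of 17, 0.0180) and oxidative stress (0.63, 0 of 10, 0.0344). The numbers higher in these 10 lists were 4, 5, 1, 4, 3, 3, 4, 5, 1 and 4 adjusted over the list alone, with 1 proliferation gene lower. Downward were periportal (-1.05, 1 of 13 lower, 5.31e-06), bile acid (-0.73, 0 of 15, 1.49e-04), complement (-0.32, 1 of 23, 1.85e-04), macrophage (-0.66, 0 of 16, 0.00172), pericentral (-0.60, 0 of 14, 0.0139), female-biased (-0.96, 1 of 10, 0.0140) and male-biased (-0.89, 1 of 6, 0.0140). The numbers lower in these 7 lists were 3, 2, 2, 0, 3, 1 and 1 adjusted over the list alone, with 1 macrophage marker higher. The other 10 lists had camera adjusted p values from 0.0569 to 0.852, and the erythroid and the Wnt and Ras pathway medians (0.07 and 0.01) were positive where camera pointed downward.

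Of the 17 lists called in HCC against BDCA_nontumor 6 lost their call without 1 array. The macrophage median became -0.06 without HCC replicate 5 (adjusted p = 0.306), which stood apart with a mean of 7.39 against 9.91 to 10.90, and the glycolysis median became 0.21 without HCC replicate 2 (0.148). The female-biased list lost its call without HCC replicate 1 or 2 (0.0701 and 0.148), and the stellate list without HCC replicate 6 (0.107) or BDCA_nontumor replicate 4 (0.0820). The pericentral list lost it without HCC replicate 1 or 6 (0.0701 and 0.121), BDCA_nontumor replicate 6 (0.110) or the 5 arrays with Xist signal (0.128). The oxidative stress list lost it without HCC replicate 2 or 5 (0.372 and 0.0628) or BDCA_nontumor replicate 1 or 2 (0.0932 and 0.0775). The other medians that moved by over 1.5 times were oncofetal 0.30, oxidative stress 0.94 and male-biased -1.42 without HCC replicate 1, and periportal -0.63, female-biased -0.59 and oxidative stress 0.41 without HCC replicate 2. They were also male-biased -0.51 and stellate 0.98 without HCC replicate 5, biliary 0.46, p53 0.27 and pericentral -0.40 without HCC replicate 6, glycolysis 0.33 without BDCA_nontumor replicate 1, and Notch and hedgehog 0.27 without BDCA_nontumor replicate 6 or the 5 arrays with Xist signal.

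In limma 256 genes passed in HCC against BDCA_nontumor, 184 higher and 72 lower, and 238 differed by at least 2-fold. The groups did not overlap in 1.52% of the tested genes, where chance gives 0.433%. With all 24 arrays as separate samples 422 genes passed, and leaving out 1 array gave 609 genes without HCC replicate 1, 136 and 130 without HCC replicates 5 and 6, and 154 and 144 without BDCA_nontumor replicates 3 and 5. The share higher, 71.9%, became 68.9% after quantile normalization and 65.4% after median centring. The values of Ctnnb1 (0.06 ± 0.15), Glul (0.25 ± 0.29), Lgr5 (0.30 ± 0.94), Axin2 (1.00 ± 0.47), Mki67 (1.67 ± 0.60), Dlk1 (-0.07 ± 0.45), Alb (-0.11 ± 0.82) and Krt19 (0.87 ± 0.53) did not pass.

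**Figure D3:**
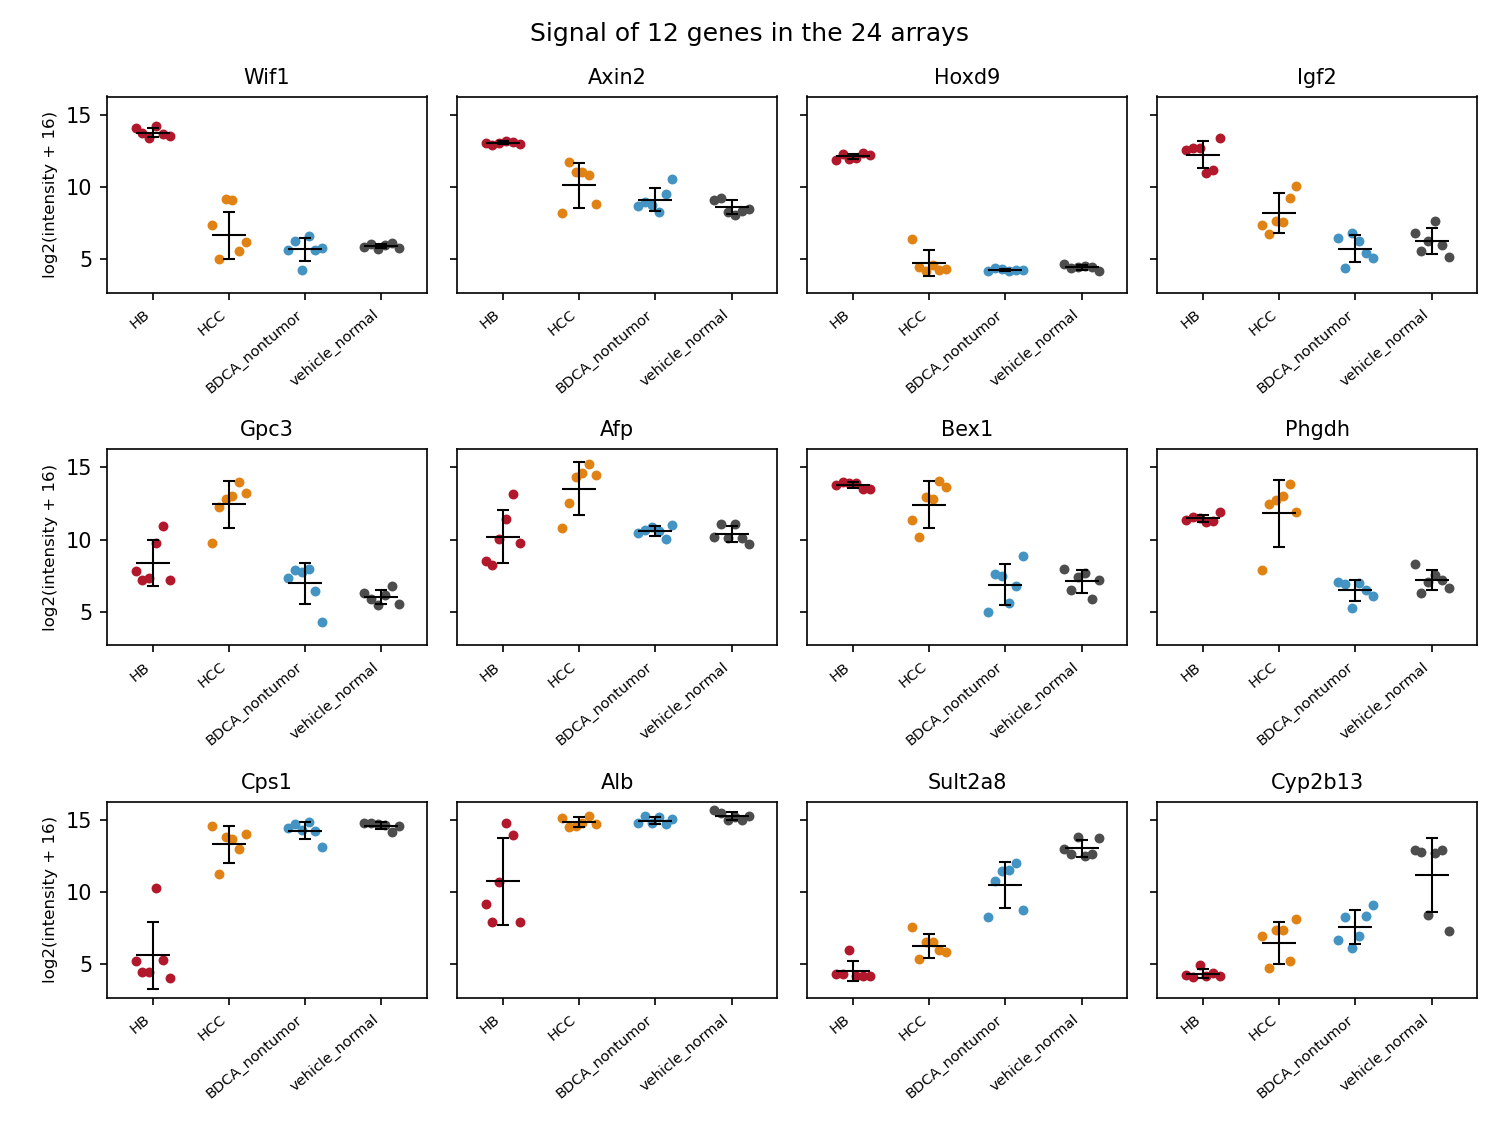
Signal of 12 genes as log2(intensity + 16) in the 24 arrays (points), with the mean and SD of the samples of each group (bars; n = 6, and n = 5 for HCC, where replicates 3 and 4 are 1 sample). Wif1, Axin2 and Hoxd9 are higher in every HB array than in every other array, while Gpc3 has its highest group mean in HCC.

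**Figure D4:**
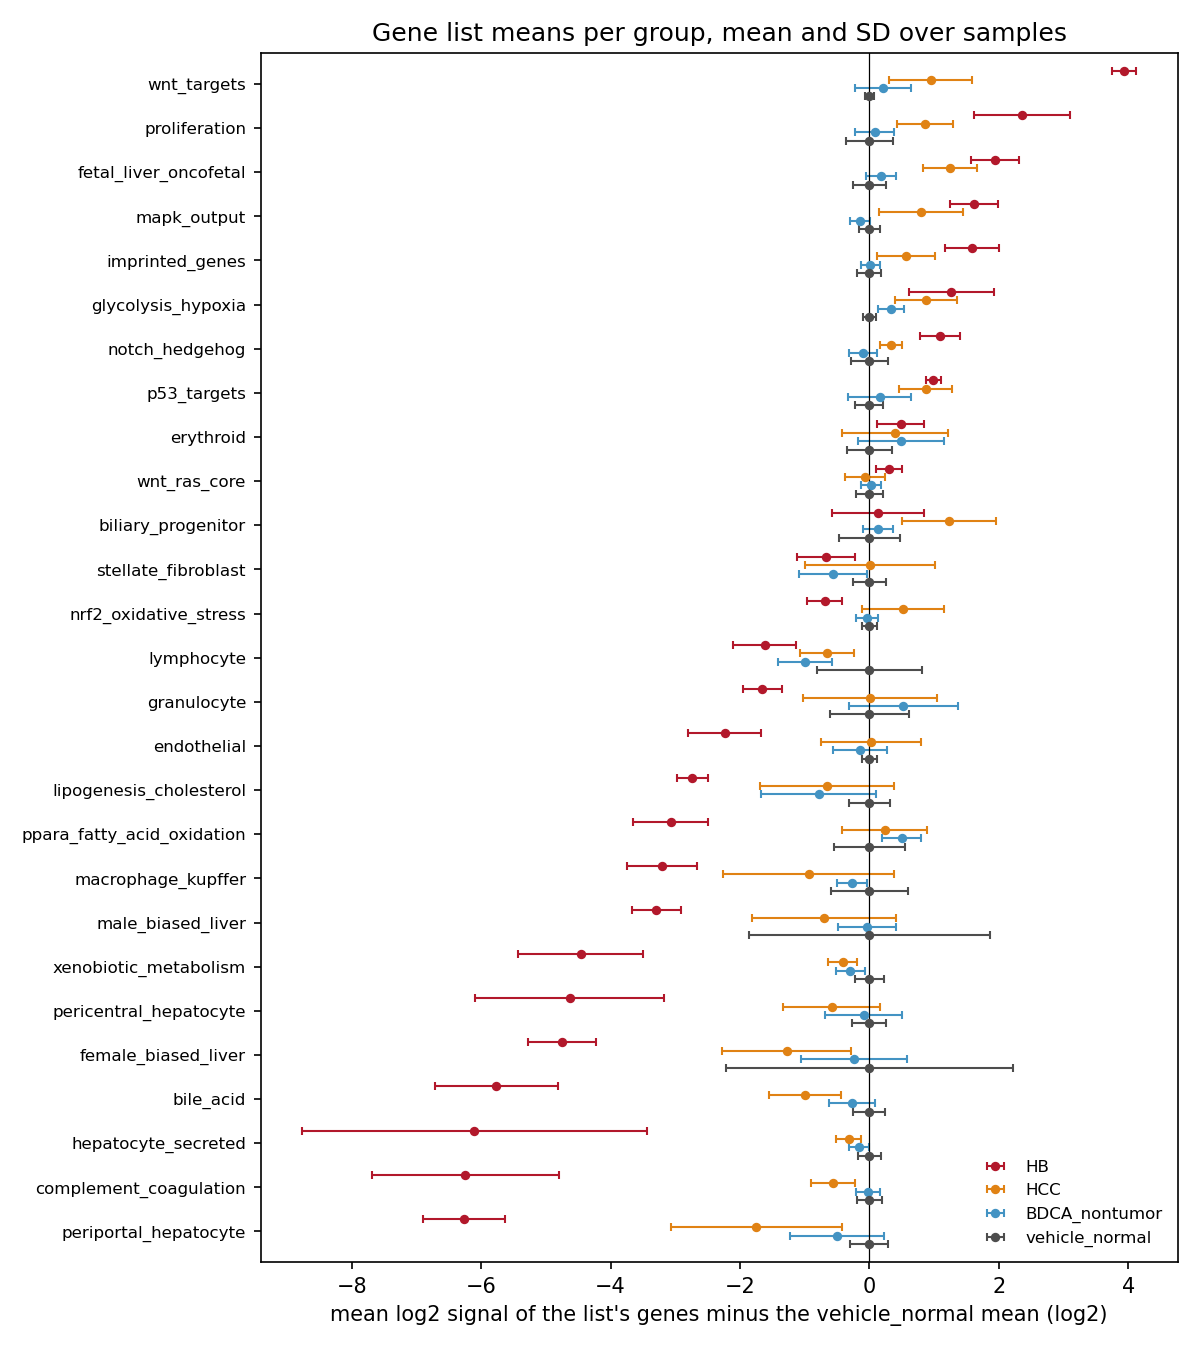
Mean log2 signal of the genes of each of the 27 lists, given as the difference from the vehicle_normal mean (mean and SD over samples; n = 6, and n = 5 for HCC). Wnt targets lie at 3.94 ± 0.18 in HB and periportal genes at -6.27 ± 0.64.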

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

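The tests of scaling by hybridization controls, of the arrays without Xist signal, of the added array measures and of genes below an intensity of 10000 were chosen only after the result was seen. Single samples lay far from the rest of their group in 48 of 532 groups of values examined (101 genes, the 27 lists and the array measures), where chance gives about 1 in 20, or 26.6. Each value below is followed by the range of the other samples of its group.

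Among the HB samples, replicate 4 had intensities of 20870.5 for Pla2g2a (4943 to 7828), 1234 for Cps1 (0.722 to 24.2), 25343 for Glul (8764 to 12662), 293 for Tff3 (8.70 to 17.1), 26.9 for Hectd2 (448 to 921), 25345 for Aldoa (10436 to 14406) and 38.3 for Timd4 (6.77 to 15.1). Its hybridization controls had a mean log2 signal of 14.05 (12.85 to 13.29). Replicate 5 had 37.0 for Upp2 (0.250 to 5.24) and 471 for C8g (80.2 to 142), and a lipogenesis list mean of 10.12 on the log2 scale (9.47 to 9.69). Replicate 2 had a Wnt target mean of 11.01 (11.39 to 11.54), and replicate 3 had 48.5 for Sult2a8 (2.00 to 4.66).

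Among the HCC samples, replicate 1 had 68.4 for Hoxd9 (2.89 to 6.33), 12283 for Slc38a4 (4714 to 5194), 5528 for Ctnnb1 (8047 to 8584) and 1031 for Slpi (5997 to 11701). Its lipogenesis mean was 9.95 (11.94 to 12.52) and its erythroid mean 9.41 (7.40 to 7.93). The sample of replicates 3 and 4 had 1156 for Hectd2 (180.1 to 254), replicate 2 had a glycolysis mean of 12.24 (11.03 to 11.32), and replicate 5 had an endothelial mean of 8.18 (9.74 to 10.11) and a macrophage mean of 7.39 (9.91 to 10.90).

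Among the BDCA_nontumor samples, replicate 1 had 69.6 for Cdkn1c (4.87 to 18.5), 4694 for Insig1 (11631 to 16547), 96.8 for Hectd2 (4292 to 8194) and 8069 for Cyp2c70 (17668 to 22855), with a xenobiotic mean of 11.60 (12.08 to 12.21) and a lipogenesis mean of 9.92 (11.59 to 12.42). Replicate 2 had a fatty acid oxidation mean of 10.84 (11.35 to 11.64). Replicate 6, which carried Xist signal, had 10428 for Cyp3a25 (17723 to 23853), 8902 for Cps1 (18937 to 29685), 2702 for Ier3 (467 to 645) and 299.956 for Timd4 (140.2 to 180.4), with a periportal mean of 10.69 (12.20 to 12.62).

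Among the vehicle_normal samples, replicate 1 had 576 for Lgr5 (176 to 230.3), and replicate 2 had 47.6 for Sox11 (89.9 to 115) and 274 for Myc (496 to 590.1). Replicate 3 had 157 for Speer4cos (3.02 to 25.1), 19515 for Upp2 (9044 to 11748), 2300.1 for Cd5l (6990.0 to 12014) and 515 for Ighm (3276 to 5485). Replicate 5 had 49.3 for Fxyd6 (2.62 to 13.3), 18008 for Cps1 (24851 to 28588) and a xenobiotic mean of 11.92 (12.32 to 12.51). Replicate 6 had 25176 for Apcs (12868 to 16371), 33.0 for Lepr (205 to 417) and a complement mean of 13.34 (12.79 to 12.94).

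Signal also appeared in probe sets without a gene name, which no comparison above used. Of 5836 such probe sets, 3416 passed in HB against vehicle_normal, 2801 higher and 615 lower, and 2556 and 2665 passed in HB against HCC and BDCA_nontumor. In HCC against vehicle_normal and BDCA_nontumor 167 and 31 passed, and in BDCA_nontumor against vehicle_normal 1.

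The groups differed in sex composition by their Xist signal, which may shift genes called against vehicle_normal. Without the 5 arrays with Xist signal, the median share of the log2 fold change kept was 0.982 over the genes called in HCC (quartiles 0.845 to 1.12, 1018 of 1019 in the same direction) and 0.941 over the 14 called in BDCA_nontumor (0.838 to 1.15, all 14 in the same direction). For the called genes these values argue against sex as the whole cause. A gene that differs by sex varies within vehicle_normal and is less likely to be called, so genes not called stay undecided. Only 153 of the 1019 calls in HCC and 3 of the 14 in BDCA_nontumor were kept, with 2 vehicle_normal arrays left. The female-biased list did turn, as given with the processing alternatives. Dose and any other treatment difference between the groups stay open, as untested.

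More genes were higher than lower in HB against vehicle_normal. If the authors' scaling to 1 trimmed mean were the cause, HB medians would not stand above the others at equal hybridization controls, but there HB lay 1.37 higher (log2), with its lowest array at 8.48 and the highest vehicle_normal array at 8.44. The controls themselves were lower in HB (13.16 ± 0.46 and 14.17 ± 0.33, SD, n = 6 each, exact test, adjusted p = 0.0433). Setting them equal could therefore only widen the gap, so this test cannot decide whether the scaling was the cause. The share higher did depend on the scaling, at 61.7% as deposited, 48.5% after quantile normalization and 46.1% after median centring. The 100 brightest probe sets held 6.05% of the summed signal in HB and 8.93% in vehicle_normal, a difference of -2.88, with every HB array below every vehicle_normal array. The trimmed mean used for the scaling leaves out the brightest probe sets. Their share therefore cannot decide whether a few abundant transcripts taking the signal in normal liver contributed. The share of probe sets above the filter was also higher in HB (66.9% and 56.1%, exact test, adjusted p = 0.0260), and a broader transcriptome of the tumour stays open, as untested.

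HB replicates 4 and 5 held more hepatocyte transcripts than the other HB samples, and RNA of surrounding liver is a candidate source. Over 36 secreted and complement genes the median share of surrounding liver was 5.64% and 5.11%, with upper over lower quartiles of 6.13 and 3.88, where 1 common share would need 2 or less and over 4 had been set beforehand to argue against it. That bound was judged wrong only after the result was seen, because the share followed the level of the gene (Spearman rho 0.745 and 0.794, across genes, which are not independent replicates), Alb reaching 89.2% and 48.0% near the ceiling of the scale. Below an intensity of 10000 the ratios of 15 genes were 3.17, between the 2 bounds, and 6.59, over 4, but resampling the genes gave 95% ranges (1.39 to 17.3 and 1.76 to 23.2) that span both bounds, so admixture and expression by the tumour cannot be told apart. No biological explanation was tested.

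Other splits of the samples were fitted, 100 of 462 for each comparison, the real one included. Only the real split gave as many genes, 1 of 100, in HB against vehicle_normal (8487, highest other 4999), HCC against vehicle_normal (1019, 248), HB against HCC (7119, 3538), BDCA_nontumor against vehicle_normal (14, 10) and HB against BDCA_nontumor (7964, 4860). That argues against a chance split of these samples, but only weakly for BDCA_nontumor against vehicle_normal, whose 14 genes fell to 2 without 1 array. Groups set against vehicle_normal also differed in Xist signal, so the splits do not tell group from sex there. In HCC against BDCA_nontumor 2 of 100 splits reached the real 256, which meets the bound of 0.05. Chance is not excluded there, because a wrong grouping called more genes than the real one. The other split exchanged HCC replicate 1 for BDCA_nontumor replicate 6 and gave 484, which points to a structure of the samples beyond the groups.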

How the results depend on the processing

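The fit of 24 separate arrays was the planned design, and became an alternative when HCC replicates 3 and 4 were merged after seeing the data. The alternatives of leaving out the Xist arrays, HB replicates 4 and 5, HCC replicates 3 and 4, or the HCC and BDCA_nontumor arrays numbered 1, were chosen only after the result was seen. The counts of HB against vehicle_normal, HCC and BDCA_nontumor stayed within 1.5 times under every alternative run, with leave-one-out ranges of 8089 to 8595, 6635 to 7199 and 7502 to 8092.

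For HCC against vehicle_normal, 193 genes passed without the 5 arrays with Xist signal (fewer samples, with 2 vehicle_normal arrays left), and leaving out 1 array gave 656 (without HCC replicate 5) to 1195 (without HCC replicate 1). For BDCA_nontumor against vehicle_normal, 9 genes passed with a pseudocount of 1, 25 with 64, 2 without the variance trend and with robust fitting, 56 with array weights, 42 with only the 2 groups, and 2 without the arrays numbered 1. Leaving out 1 array gave 9 without HB replicate 1, 33 and 23 without HCC replicates 1 and 5, 2, 3, 7 and 7 without BDCA_nontumor replicates 1, 3, 4 and 5, and 3, 3 and 2 without vehicle_normal replicates 1, 2 and 4. For HCC against BDCA_nontumor, 562 passed with array weights, 72 with only the 2 groups and 568 without the arrays numbered 1. As 24 separate arrays 422 passed. The replicate block was also fitted on 24 separate arrays and gave 387, or 415 as a random block, so both compare with 422. Leaving out 1 array gave 609, 136 and 130 without HCC replicates 1, 5 and 6, and 154 and 144 without BDCA_nontumor replicates 3 and 5. Apart from fits with fewer samples, the cause was not tested.

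The replicate numbers did not pair the samples as a set: same-numbered arrays had r over genes between -0.10 and 0.03 for HB and HCC, the consensus correlation with BDCA_nontumor included was -0.00348, and 1 of 6 HCC arrays correlated most with its own number in BDCA_nontumor. That was replicate 1, at r = 0.505, where the other 5 pairs had at most 0.101.

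Of 86 list shifts 17 held with an estimated correlation, which widens the test where the estimate exceeds the preset 0.01. The overlap of 770 genes became 256 and 301 with separate controls, which had 3 vehicle_normal arrays each. Both stayed above the numbers from independent calls. Tpi1 in HB against HCC reversed to 0.011 after quantile normalization. Without the Xist arrays 2 list tests reversed, where a list not called before counts only if it passes in the opposite direction. The female-biased list reversed in HCC against vehicle_normal, from a median of -1.41 to 1.60. In BDCA_nontumor its median, already positive at 0.39 and not called, became 2.73, and camera turned from downward to upward. All tested members except Cyp17a1 and Prom1 were higher in every vehicle_normal array with Xist signal than in the 2 without. Cyp2b13, for example, read 6749 to 7898 against 333 and 143. Leaving the Xist arrays out therefore lowered the vehicle_normal level of this list. The cause of the change in Tpi1 was not tested. Of the named genes called, 13 of 44 in HCC and 8 of 10 in BDCA_nontumor against vehicle_normal lost their call in some leave-one-out fit, and none reversed. Lists that lost their call in some leave-one-out fit were 7 of 16 in HCC and 1 of 3 in BDCA_nontumor against vehicle_normal, 1 of 15 in HB against HCC and 6 of 17 in HCC against BDCA_nontumor. Probe sets without 6 values above an intensity of 66.3 were not tested. Genes with a whole group below it were, and the size of their folds depends on the pseudocount.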

Other observations

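All tests in this part were chosen only after the result was seen, so each is a hypothesis found and tested on the same data.

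Hoxd8 and Hoxd9 were among the genes most raised in HB, and Hox genes as a family may be higher there. The 11 other tested Hox genes had a median of -0.62 against 0.34 for all genes, so most of them did not rise. Camera with an estimated correlation pointed upward (p = 0.9997, exact tests were not run). With large differences in both directions it cannot decide on the family as a whole. Hoxd3 (2.58), Hoxd10 (6.46) and Hoxd11 (5.62) were higher, and Hoxa3 (-1.84), Hoxa7 (-1.18), Hoxb3 (-1.23) and Hoxb4 (-1.42) lower, in HB against vehicle_normal (log2, n = 6 each).

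Phgdh was raised in HCC, and other enzymes of serine synthesis and one-carbon metabolism may rise with it. In HCC against BDCA_nontumor 7 such genes had a median of 1.38 and p = 0.00391 in camera with an estimated correlation (no exact test was run), though only Psat1 passed by itself (4.49 ± 0.61, SE, adjusted p = 1.74e-04). Shmt1 (-0.37) and Shmt2 (-0.68) lay lower there without passing. A rise was not particular to HCC: in HB against BDCA_nontumor the median was 1.55, with 5 genes called higher and 2 lower (camera with an estimated correlation, p = 0.542).

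Sult3a1 read between 1025 and 13426 in the 5 BDCA_nontumor arrays without Xist signal and 26.6 and 21.7 in the 2 such vehicle_normal arrays, and female-predominant genes as a group may be raised there. The 9 other members of the list had a mean 2.10 higher on the log2 scale (9.95 and 7.86, 7 of 9 higher, exact permutation p = 0.0476, the smallest that 21 splits can give). These 7 arrays all carried Y-linked signal (Eif2s3y 1733 to 2669, Kdm5d 689.5 to 1451), which argues against a difference in sex between them. Treatment and the tumours nearby were not separated.

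Speer4cos and Speer8-ps1 rose in HB by 8.40 and 7.38 on the log2 scale, Speer4a by 6.88 and Speer4b by 6.59, while Speer4f1 stood at 0.88 (adjusted p = 0.121). These genes are close paralogs, and whether their probe sets read different transcripts was not analysed here.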
